A study of Sus scrofa with 12 samples.

How the data were processed

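Muscle RNA of 12 pigs was sequenced, with 6 animals labelled high drip and 6 labelled low drip, and 3 females and 3 males at each level. Drip loss is the water that meat loses after slaughter, and a high value means a low water holding capacity. Per the labels, RNA was extracted with Trizol and treated with DNase, and libraries were made with the TruSeq v2 kit and run on a Genome Analyzer IIx. The authors aligned reads with TopHat2 2.0.3 and Bowtie 0.12.7.0 to the pig build Sscrofa10.2 and counted them with HTSeq, with no parameters stated. The deposited values are raw counts per gene, in 2 tables per animal. The first covers the whole annotation, and the second covers chromosomal regions with loci for water holding capacity. The strand setting and the annotation release are not stated.

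The whole-genome table held 20741 features, of which 20300 were Ensembl genes and 441 carried HSMMG identifiers, which no table used here pairs with a gene. The region table held 770 features, 329 of them Ensembl genes, and all 770 were found in the whole-genome table. Symbols were taken from a table of gene IDs by exact match, which named 10349 of the 20300 Ensembl genes. No genome sequence, gene length or GC content was used here.

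Each animal's region table was compared with every whole-genome table by the number of identical counts and by Spearman correlation. For 9 animals the recorded whole-genome table was the best match. For the other 3, all female, the table recorded for the animal matched another animal, whose number it also carried in its name. The region tables carried their own animal's number. These 3 animals were left out of the whole-genome drip fits. Those fits therefore held 5 high drip animals, 2 of them female, and 4 low drip animals, 1 of them female. Counts per library ranged from 8009627 to 12622043 in the whole-genome tables and from 137166 to 199407 in the region tables. CPM is counts scaled to the total of the tested features with TMM factors, except for albumin and the liver markers, which are scaled to the whole table's total, and intervals and floors cover counting error only.

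Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood F-test, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Folds are on the log2 scale, high minus low drip or male minus female, with the standard error of the fit, and means are given with the SD over animals. The drip fits had sex as a term, the interaction fits had sex, drip and their product, and the sex fit had no other term. The interaction is the high minus low difference in males less that in females. The comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took up to 12 genes each way past the threshold (8 in the region tables). Where fewer than 10 passed, it took the 10 with a symbol and the smallest p, together with 3 members of each list and 12 genes always given. Of those 12, RYR1, CAST, MYH7, MYH4, ADIPOQ and FABP4 had no ID with that symbol. One gene that the rule took in the region tables is not reported here and was not replaced.

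Gene lists were tested with limma 3.58.1 (camera on voom values, preset correlation 0.01), adjusted over the 23 lists with at least 3 measured members, with camera's estimated correlation and fry beside it. The lists were slow fibre, fast fibre, calcium release and coupling, glycogen and glycolysis, nuclear oxidative phosphorylation, citrate cycle and fatty acid oxidation, adipocyte and lipogenesis, extracellular matrix, sarcomere anchor and costamere, calpain, cathepsin and atrophy, proteasome, heat shock, immediate early, redox and metallothionein, water, ion and acid transport, ribosome, growth signalling, and markers of macrophages, lymphocytes, endothelial cells, smooth muscle and pericytes, fibroblasts, and satellite cells and myoblasts. The erythroid list had 1 measured member, the Schwann cell list 2, and the mitochondrially encoded and both sex-linked lists 0, so these were not tested and the sex labels were not checked from expression. A list's score per animal is the mean over its members of log2 CPM less the member's mean.

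The share of region features with an unadjusted p under 0.05 was compared with 10000 random sets of tested features matched on 10 bins of expression. The steps were tested on simulated data, with known changes placed in counts drawn from a negative binomial with each gene's mean and dispersion. Apart from these changes the drawn counts held no differences between groups of animals, so the recovered shares may be higher than in the real data. At the drip fit's size, 16.4% of changes of 1.5-fold, 56.7% of changes of 2-fold and 93.9% of changes of 4-fold were recovered. In the region tables these shares were 50.0%, 75.0% and 100%, and for sex 32.8%, 85.1% and 98.5%. For the interaction they were 0%, 30.0% and 40.0% in the region tables and 0%, 1.49% and 40.9% in the whole genome. Of the calls, 5 of 116 for drip, 5 of 50 in the region tables and 11 of 155 for sex were false, as were 0 of 14 for the region interaction and 6 of 34 for the whole-genome interaction. A list moved by 0.3 on the log2 scale was found, with 0 other lists called. The simulated genes were independent of each other, so this does not measure false list calls where members move together, as in the real lists.

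Alternatives were other scaling (RLE), other tools (DESeq2 1.42.0 and limma voom), other filters on low counts, other covariates, other readings of the 3 conflicting tables, and leaving out each animal. A split of the libraries by liver transcripts, at an albumin level above 10 CPM, was chosen after its values were seen. So were the 25 liver markers, the tests on PRKAG3, the alternatives that use the split, the region fits with the drip labels of the whole-genome records, the region interaction in 9 animals, and the region test on Ensembl genes alone. The rule for testing the liver split on the called lists first used the 9 animals alone, where all 4 lists met it. It was revised 3 times after values were seen. A stricter rule on 2 groups of lists was dropped, since the groups had been chosen from the values it tested, and a count over the fits on 9 and 12 animals replaced it. The rule used here is the same for each list and asks for the call in both fits and in all 21 fits that leave out 1 of their animals, which were run after it was written. Splits of the same animals into groups of the same sizes numbered 100, the real one included, for each fit with at least 3 animals per group.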

Results

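Muscle transcripts were counted in 12 pigs aged 167 to 189 days. The 6 high drip animals were 176 ± 6.92 days old and the 6 low drip animals 178 ± 6.74 days old (mean ± SD), with 3 females and 3 males in each group. The whole-genome tables held a median of 9749100 counts per library, from 8009627 to 12622043. The region tables held from 137166 to 199407 counts. Between 13183 and 14047 features had a count in each library, and the correlation of log2 CPM between libraries was 0.960 to 0.979 across genes, which are not independent replicates.

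The 2 tables of an animal shared 737 to 745 identical counts of 770 when they came from the same library, and at most 167 otherwise. Low drip replicate 1 matched the whole-genome table recorded for low drip replicate 2, high drip replicate 2 matched that recorded for low drip replicate 1, and low drip replicate 2 matched that recorded for high drip replicate 2. The recorded tables of these 3 females shared 123, 136 and 136 counts with their region tables. With tables taken by match, all 12 animals had the same total of alignments in both tables.

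Transcripts of liver secretory genes were present in 6 of the 12 libraries. ALB, which encodes serum albumin, lay between 25.6 and 317 CPM in high drip replicates 1, 2, 3 and 4 and low drip replicates 5 and 6, and between 0.327 and 2.49 CPM in the other 6. Of 25 liver markers, 14 were higher in each of these 6 libraries than in any other, among them TF (transferrin), APOC3 and AHSG. With animals labelled by their region tables, all 3 high drip females and 0 of the 3 low drip females had liver transcripts, against 1 of 3 high drip and 2 of 3 low drip males. With the labels recorded for the whole-genome tables it was 2 of 3 high drip and 1 of 3 low drip females. In a fit on all 12 matched libraries with sex and drip as terms, 10 of 10093 genes differed between libraries with and without liver transcripts at the 0.05 threshold. The 5 higher genes were the liver markers APOC3, ALB, AHSG, AMBP and FGB. Since ALB above 10 CPM defines the split, its call was fixed by the grouping, and those of markers that vary with it give no separate support. The 5 lower ones were PRKAG3 and 4 unnamed HSMMG features, with a fold of -0.82 ± 0.09 for PRKAG3 (adjusted p = 0.00461).

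**Figure D1:**
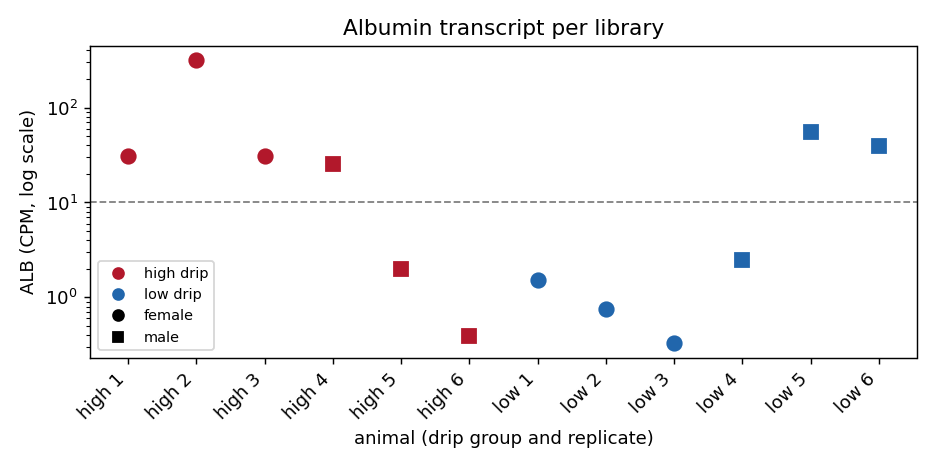
Albumin (ALB) transcripts in CPM on a log axis, one point per library for the 12 animals, coloured by drip group, with circles for females, squares for males and a dashed line at 10 CPM. The 6 libraries at 25.6 to 317 CPM stand above the 6 at 0.327 to 2.49 CPM.

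The first comparison asked which muscle transcripts differ between pigs with high and low drip loss. The smallest p among genes with a symbol belonged to NOVA1, a splicing factor, at 1.88 ± 0.603 CPM in 5 high drip and 3.93 ± 0.962 CPM in 4 low drip animals (fold -0.95 ± 0.20). SLC12A2, the sodium, potassium and chloride cotransporter, had 60.9 ± 11.4 against 106 ± 30.0 CPM (fold -0.79 ± 0.22). AGT, the precursor of angiotensin, had 17.0 ± 3.14 against 26.7 ± 6.87 CPM (fold -0.55 ± 0.15), and TBC1D7, a subunit of the TSC complex, 24.6 ± 5.60 against 41.3 ± 7.40 CPM. CHGA, PITX3, SLC30A2, WIPI1 and ADAMTS8 had folds from -2.31 to -0.40, and NTMT2 had 0.59. None of these passed the threshold, and each had an adjusted p of 0.999. In the females left out of this fit, by matched tables, TBC1D7 was at 33.0 CPM in high drip replicate 2. It was at 18.4 and 16.5 CPM in low drip replicates 1 and 2, against the direction of the fit. NOVA1 and NTMT2 also went against the fit in these animals. AGT, SLC30A2, WIPI1 and SLC12A2 went with it, and for CHGA, PITX3 and ADAMTS8 high drip replicate 2 lay between the low drip females.

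Of the genes always given, PHKG1, a catalytic subunit of phosphorylase kinase, which starts glycogen breakdown, had 219 ± 34.2 CPM in high and 168 ± 23.2 CPM in low drip animals (fold 0.36 ± 0.15). PRKAG3, a muscle subunit of the AMP-activated kinase, had 136 ± 34.7 against 111 ± 52.5 CPM (fold 0.31 ± 0.27). The folds of CAPN1, PYGM, LDHA and HBB were -0.01, -0.01, 0.04 and 0.49. Without low drip replicate 3 the folds of HBB and PHKG1 were 0.02 and 0.21, and without high drip replicate 6 that of PRKAG3 was 0.12. With edgeR, 0 of 10228 features passed, and 231 had an unadjusted p under 0.05 where chance alone gives 511.4. With voom 0 passed and 235 had such a p, and with DESeq2 5 passed, 1 higher and 4 lower. One of those 5, DBH, had counts in 1 library only, at most 4, and 2 genes passed in edgeR without low drip replicate 4. With all 12 animals by matched tables, FKBP5, a cochaperone induced by glucocorticoids, was at 63.4 ± 13.2 CPM in 6 high and 127 ± 46.1 CPM in 6 low drip animals (adjusted p = 0.999).

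In the gene lists, 4 of 23 passed for drip. Adipocyte and lipogenesis genes were lower in high drip animals, with 12 of 14 measured members lower and 2 higher and a median fold of -0.30 (camera adjusted p = 0.000687, and 0.869 with an estimated correlation). FASN, the fatty acid synthase, had 26.5 ± 13.5 against 49.8 ± 19.6 CPM, and the lipid droplet genes CIDEC and PLIN1 had folds of -0.76 and -0.66. Redox and metallothionein genes were higher, with 13 of 14 members higher and a median of 0.15 (adjusted p = 0.000687, and 0.121 with an estimated correlation). The quinone reductase NQO1, GCLC, which makes glutathione, and the peroxiredoxin PRDX1 had folds of 0.28, 0.29 and 0.22. In the females left out, by matched tables, PRDX1 went the other way, at 35.8 CPM in high drip replicate 2 against 54.6 and 58.8 CPM in low drip replicates 1 and 2. NQO1 and GCLC kept their direction there. Nuclear genes of oxidative phosphorylation were higher in 27 of 36 members with a median of 0.07 (adjusted p = 0.0186, and 0.914 with an estimated correlation), with 0.17 for NDUFA9 and 0.16 for NDUFB7. Immediate early genes, which respond quickly to stimulation, were lower in 13 of 15 members with a median of -0.38 (adjusted p = 0.0197, and 0.914 with an estimated correlation). FOS had 167 ± 108 against 391 ± 357 CPM, and CCN1 had a fold of -0.85. Several of these folds lean on 1 animal, and the weakest value without any 1 was -0.48 for FOS (main value -1.27) and -0.44 for CCN1, both without low drip replicate 5. It was -0.40 for CIDEC and -0.39 for PLIN1 without low drip replicate 6, 0.15 for GCLC without low drip replicate 4 and 0.07 for PRDX1 without low drip replicate 3. For NDUFA9 it was 0.11 without high drip replicate 5.

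None of these members passed, over all genes or adjusted over the list alone, and no list was called with an estimated correlation. The mean score of the redox list was 0.079 ± 0.069 in 5 high and -0.068 ± 0.047 in 4 low drip animals (two-sided exact permutation p = 0.0238, adjusted p = 0.548 over 23 lists). Of 100 splits of the same 9 animals, the real one included, 73 called at least 4 lists. Of the other splits, 97 called at least 1 list, and their median was 5. The 4 calls are thus no more than arbitrary groups give, and chance is not excluded for them. The oxidative phosphorylation call ended without high drip replicate 4 (adjusted p = 0.649), low drip replicate 4 (0.476), high drip replicate 5 (0.0646) or low drip replicate 6 (0.0826). The immediate early call ended without high drip replicates 1 (0.0756), 3 (0.106), 5 (0.364) or 6 (0.160) or low drip replicates 3 (0.736) or 5 (0.669). In the 4 libraries without liver transcripts, where drip is compared in males alone, immediate early genes were higher in high drip animals (adjusted p = 0.00419). That contrast rests on 1 low drip male, low drip replicate 4, whose score of -0.97 for this list was the lowest of the 12 animals and whose spread is taken from the others.

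**Figure D2:**
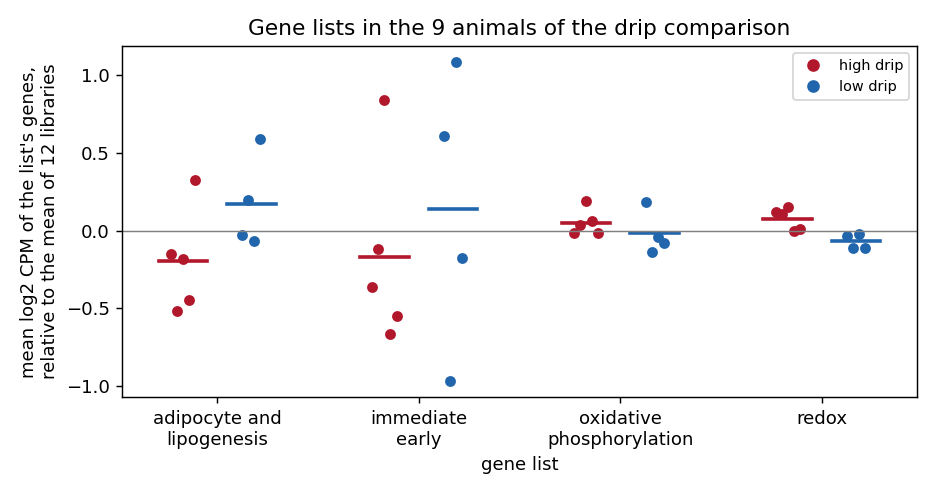
Scores of the 4 gene lists called for drip, as mean log2 CPM of each list's genes relative to the mean of 12 libraries, with one point per animal for 5 high and 4 low drip animals and a bar at each group's mean. The redox scores are 0.079 ± 0.069 in high and -0.068 ± 0.047 in low drip animals (mean ± SD), and the groups overlap in the other lists.

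The other 19 lists were not called for drip in this fit, although some were called in alternatives, such as glycogen and glycolysis genes (higher) with all 12 animals by matched tables and fibroblast markers (lower) with age added. Among those of the contractile fibre, the adjusted p was 0.305 for slow fibre genes (median 0.07), 0.707 for fast fibre genes (0.04), 0.861 for calcium release and coupling (-0.02) and 0.186 for sarcomere anchor and costamere genes (-0.11). In metabolism it was 0.394 for glycogen and glycolysis (0.01) and 0.707 for the citrate cycle and fatty acid oxidation (-0.02). For protein turnover and growth it was 0.861 for calpain, cathepsin and atrophy genes (0.03), 0.861 for the proteasome (0.02), 0.332 for heat shock (-0.05), 0.394 for the ribosome (0.04) and 0.861 for growth signalling (-0.02). It was 0.461 for water, ion and acid transport (-0.04) and 0.276 for the extracellular matrix (-0.11). Among markers of other cells, lymphocyte markers were higher in 6 of 6 members with a median of 0.37 (adjusted p = 0.186). The adjusted p was 0.908 for macrophage markers (0.02), 0.524 for endothelial (0.12), 0.908 for smooth muscle and pericyte (0.02), 0.193 for fibroblast (-0.14) and 0.83 for satellite cell and myoblast markers (-0.08). The median and the test differed in sign for the calpain and macrophage lists, and the mean and the median differed in sign for the calcium, calpain, growth and macrophage lists.

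The region tables addressed genes under the loci for water holding capacity, with all 12 animals. TNRC6B, a partner of Argonaute in silencing by small RNAs, had 212 ± 69.5 CPM in 6 high and 306 ± 26.8 CPM in 6 low drip animals (fold -0.53 ± 0.22), and OTUD7B, a deubiquitinase, 3711 ± 217 against 4441 ± 792 CPM (fold -0.25 ± 0.11). DDB1, a DNA damage binding protein, had a fold of -0.16 ± 0.08, and NR3C1, the glucocorticoid receptor, -0.28 ± 0.19, which was -0.08 without low drip replicate 5. SLC20A2, CPSF7 and IMPDH2 also had negative folds, while SMDT1 had 0.47 ± 0.28 (0.27 without high drip replicate 3) and SAE1 0.13 ± 0.09. In the whole-genome tables SMDT1 was nearly absent in high drip replicate 4, at 0.184 CPM against 6.31 to 51.0 CPM in the other animals. In libraries with liver transcripts, where that animal is the only high drip male, its whole-genome fold was -6.34. PRKAG3 had 0.13 ± 0.21 (-0.04 without high drip replicate 6), and the feature with the smallest p, HSMMG85, 0.54 ± 0.17. With edgeR 0 of 440 features passed (smallest adjusted p = 0.992), and 13 had an unadjusted p under 0.05 where chance gives 22. DESeq2 and voom each gave 0, with 12 and 6 such features. For 3 of the females the 2 tables conflict on the animal, and the region labels used here are those on the region tables. The match of the counts and the numbers in the names of the tables go with these labels and against the whole-genome records. With the labels of the whole-genome records 0 passed and 8 had such a p, and SLC20A2 changed sign to 0.13.

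Region features were set against the rest of the genome for how often they differed by drip. An unadjusted p under 0.05 was found for 10 of 456 region features (2.19%) and 221 of 9772 others (2.26%), and random sets gave a median of 2.41% (two-sided permutation p = 0.709 over 10000 sets of features drawn within expression bins, with genes not independent). Among the 203 Ensembl genes of the regions alone the count was 0, below the random median of 1.97% (permutation p = 0.0214), a test chosen after the values were seen. All 10 region features with such a p were thus HSMMG features, while the features outside the regions were all Ensembl genes. The shares of 2.19% and 2.26% therefore compare unlike kinds of feature.

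The next comparison asked whether the drip difference itself differed between males and females. In the region tables, PRKAG3 was at 7607 ± 393 CPM in high and 9909 ± 458 CPM in low drip females, and at 8725 ± 2818 CPM in high and 5531 ± 1328 CPM in low drip males (n = 3 each). Its interaction was 1.04 ± 0.31 (edgeR adjusted p = 0.383), and it was 0.09 ± 0.26 with the liver transcript split as a term (adjusted p = 0.989). With the drip labels recorded for the whole-genome tables, high drip females had 8265 ± 1285 CPM and low drip females 9251 ± 1399 CPM. The interaction was then 0.82 ± 0.34 (adjusted p = 0.684), and 0.45 ± 0.21 with the split as a term (adjusted p = 0.973). In the 9 animals without a conflict it was 1.08 ± 0.45 (edgeR adjusted p = 0.702), and 0.12 ± 0.32 with the split. CYP2E1, a cytochrome of the liver, was at 141 ± 91.4 CPM in high drip females and had 0 counts in the 3 low drip females, which allows up to 19.9 CPM per library at a floor of 3 counts. It was at 11.5 ± 14.5 CPM in high and 59.4 ± 66.4 CPM in low drip males. INPP5A, PMM1, NDUFA6 and LAMB2 had interactions from 0.49 to 0.80, and the unnamed HSMMG165 2.81 ± 0.55 (edgeR adjusted p = 0.103). TCP11L2, NR3C1 and H2AZ2 had -0.98, -0.79 and -0.52. NR3C1 had -0.40 without low drip replicate 5, and H2AZ2 had -0.30 without high drip replicate 3. With edgeR 0 of 485 features passed and 27 had an unadjusted p under 0.05. Without high drip replicate 4, 4 passed in edgeR, including PRKAG3 (1.26, adjusted p = 0.0362), and without low drip replicate 4, 3 passed. These are the only high drip male with liver transcripts and the only low drip male without them. Leaving out either one aligns the liver split more closely with sex and drip. Apart from HSMMG323, the features that passed were the liver marker CYP2E1 or features that also differed by the split. The split is therefore not excluded for these calls.

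Grouped by liver transcripts, PRKAG3 was at 6378 ± 1441 CPM in the 6 libraries with them and 9542 ± 1425 CPM in the 6 without (two-sided exact permutation p = 0.00866 over 924 regroupings). The unnamed feature HSMMG187 was at 5959 ± 1679 against 9253 ± 2118 CPM (exact p = 0.0173). Both features were chosen after their values were seen. Across the 12 animals the 2 features had r = 0.976 and rho = 0.951, each with a permutation p of 1e-05, the smallest the permutations can give. Without the 2 animals farthest from the median r was 0.954. Within the 6 libraries with liver transcripts r was 0.984 (exact p = 0.00417) and rho 0.943 (exact p = 0.0167), and within the 6 without r was 0.936 (exact p = 0.0208) and rho 0.657 (exact p = 0.175). Of 439 features compared with PRKAG3, 5 passed (adjusted permutation p = 0.00293 for HSMMG187), and the next highest r was 0.926 for TMED4.

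**Figure D3:**
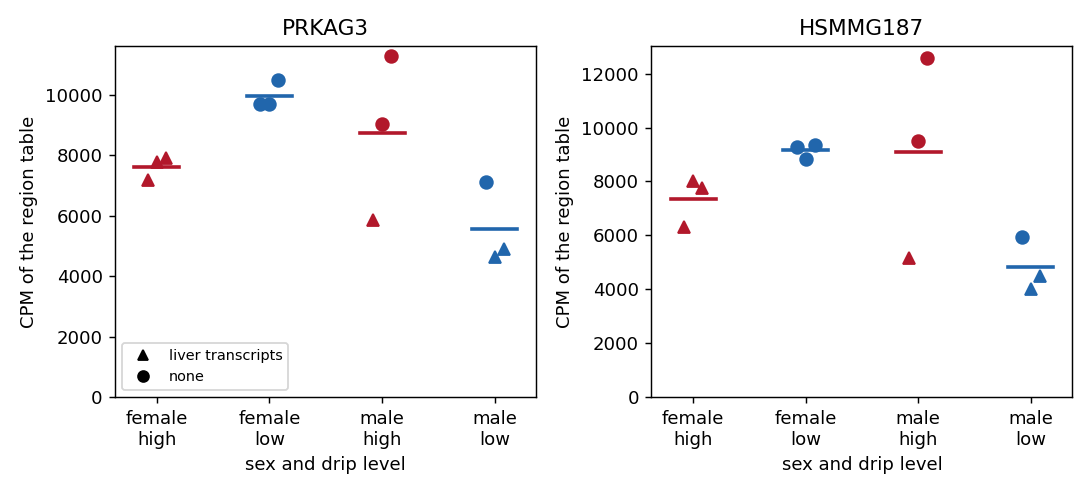
PRKAG3 (left) and the unnamed feature HSMMG187 (right) in the region tables, in CPM, one point per animal by sex and drip level, with triangles for libraries with liver transcripts, circles for those without and a bar at each group's mean. PRKAG3 averages 6378 CPM in libraries with liver transcripts and 9542 CPM in those without, and in females the split and the drip group coincide.

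In the whole-genome tables the interaction rested on 1 low drip female, low drip replicate 3, whose spread is taken from the other groups. IRS1, the insulin receptor substrate, had an interaction of 1.76 ± 0.25 (adjusted p = 0.362), SLC25A25, a mitochondrial carrier of ATP and magnesium, 2.03 ± 0.36, and ATP6V0D1, a subunit of the proton pump of lysosomes, 1.64 ± 0.28. OPLAH, PHGDH, PLIN4 and SAT2 also had positive values and CSPP1, IKZF2 and TCP11L2 negative ones. With edgeR 0 of 10228 features passed and 651 had an unadjusted p under 0.05 where chance gives 511.4. Without high drip replicate 5, 1 passed.

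Males and females were compared over all 12 animals. MAPKAPK3, a stress kinase, was at 58.3 ± 4.50 CPM in 6 males and 84.8 ± 14.3 CPM in 6 females (fold -0.54 ± 0.11), and FHOD1, a formin that acts on actin, at 206 ± 19.7 against 274 ± 26.5 CPM (fold -0.41 ± 0.09). TEX9 was at 27.9 ± 6.70 against 12.6 ± 5.77 CPM (fold 1.16 ± 0.27). LIPT2, NIPSNAP3A, FAM174A, LRRC2 and TPX2 had folds from 0.39 to 0.70, and CIAPIN1 and PLEKHB1 -0.38 and -2.30. The nuclear receptor NR4A3 was at 118 ± 130 CPM in males and 20.3 ± 11.6 CPM in females. Only the males with liver transcripts stood high, at 352 (low drip replicate 5), 165 (high drip replicate 4) and 126 CPM (low drip replicate 6). The other males had 9.67 to 31.1 CPM, within the 7.53 to 37.7 CPM of the females. Females with liver transcripts had 7.53 to 30.0 CPM. With edgeR 0 of 10093 features passed (smallest adjusted p = 0.532), and 711 had an unadjusted p under 0.05 where chance gives 504.65. With voom 0 passed and 701 had such a p. DESeq2 called 13, 6 higher and 7 lower in males, among them MAPKAPK3, FHOD1, TEX9, NIPSNAP3A, FAM174A and CIAPIN1.

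Extracellular matrix genes were higher in males in 14 of 17 members with a median of 0.19 (camera adjusted p = 0.0208, and 0.805 with an estimated correlation), with folds of 0.49 for THBS4, 0.44 for FMOD and 0.49 for FBN1. Fibroblast markers were higher in 6 of 6 members with a median of 0.24 (camera adjusted p = 0.0337, and 0.805 with an estimated correlation). PDGFRA had a fold of 0.42, LUM 0.27 and DCN 0.24, and DCN had 0.15 without high drip replicate 1. Sarcomere anchor and costamere genes were lower in 12 of 13 members with a median of -0.11 (adjusted p = 0.0301, and 0.805 with an estimated correlation), with -0.34 for TLN2 and -0.26 for the intermediate filament DES. Of 100 splits of the 12 animals, the real one included, 78 called at least 3 lists. The median of the other splits was 4 lists, so the 3 calls are no more than arbitrary groups give, and chance is not excluded. All 3 calls ended without high drip replicate 3 (adjusted p = 0.142 each) or high drip replicate 4 (0.209 for the matrix, 0.164 for fibroblast and 0.0638 for costamere genes). Over the 12 fits that each leave out 1 animal, the fibroblast call was lost in 9 (adjusted p up to 0.172), the costamere call in 7 (up to 0.178) and the matrix call in 3.

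No member of these lists passed over all genes. Adjusted over the list alone, 5 members passed, which were the calcium channel subunits CACNG1 (-0.41) and CACNB1 (-0.34) and ASPH (0.39) of the calcium list, NR4A3 (2.55) of the immediate early list and NCAM1 (-0.64) of the satellite cell list. The value of NR4A3 rests on the males with liver transcripts. Among the uncalled lists, the adjusted p was 0.245 for calpain, cathepsin and atrophy genes (median -0.12), the proteasome (-0.09) and the ribosome (-0.04), and 0.297 for the citrate cycle and fatty acid oxidation (0.05). It was 0.359 for slow fibre (-0.03), fast fibre (-0.12), calcium release and coupling (-0.05), glycogen and glycolysis (-0.08), adipocyte and lipogenesis (0.12), immediate early (-0.28) and growth signalling genes (-0.04), and for lymphocyte (-0.31) and endothelial markers (0.06). It was 0.410 for macrophage (-0.19) and satellite cell and myoblast markers (-0.34), 0.516 for redox and metallothionein (-0.04), 0.563 for heat shock (0.08) and 0.649 for smooth muscle and pericyte markers (0.07). It was 0.806 for oxidative phosphorylation (0.01) and 0.835 for water, ion and acid transport (-0.05). The mean and the median differed in sign for fast fibre genes (mean 0.01) and for oxidative phosphorylation (mean -0.01).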

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

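The tests on liver transcripts, on the liver split of the lists, on the correlation within lists and on PRKAG3 were chosen after those values were seen, and the splits for the gene counts were drawn when the counts of 0 were known. A value that stands far from the rest of its group is given here, and 18 of 220 groups of values held one, where about 1 in 20, or 11, arises by chance. Many of these values are of genes picked by their p in the same data, which can favour such values. The 18 against 11 therefore shows no excess over chance.

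Liver transcripts set 6 libraries apart, and albumin reached 317 CPM in high drip replicate 2 against at most 30.9 CPM in the other high drip animals. High drip is not needed for them, since 2 low drip animals whose tables match carry them. A link with drip is not excluded by this. By the region labels all 3 high drip and 0 of the 3 low drip females carry them, against 1 of 3 high and 2 of 3 low drip males. The 25 liver markers keep a similar order of abundance in the library with the most and in the other 5 together (rho = 0.878), which may point to liver RNA or reads carried into these libraries. Whether they came in at sampling, in library preparation or in sequencing stays open, as does expression in the muscle itself, and no other biological explanation was tested. The cytochromes CYP2D6 (325 CPM in high drip replicate 2 and 119 CPM in low drip replicate 5) and CYP2E1 (132 CPM in low drip replicate 5) stood apart in the same region tables.

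The 4 lists called between high and low drip were weighed against correlated members, the liver split and arbitrary groups. With the liver split as a term all 4 stayed called in the 9 animals and 3 of the 4 in all 12 animals by best match, where the adipocyte list had an adjusted p of 0.0545. Leaving out each animal in turn from these fits, with the liver split kept as a term, the call held in 11 of 21 fits for the adipocyte list, 16 for oxidative phosphorylation, 17 for immediate early and 20 for redox. The oxidative phosphorylation call held in all 12 of the larger fits, but ended in 5 of the 9 smaller ones (adjusted p = 0.801 without high drip replicate 4), and the redox call ended once (0.0672 without low drip replicate 6). No list kept its call in all 21, which was asked of each before these fits were run, so the liver split is not excluded for any of them. For oxidative phosphorylation and immediate early the rule cannot decide. Their calls also ended without the split as a term, in 4 and 6 of the 9 fits that leave out 1 animal, so a lost call need not come from the split. The split cannot be told apart from drip in females by the region labels, so only males separate them. With the split as a term the adipocyte, oxidative phosphorylation and immediate early calls also hang on single animals in the fits on 9 animals, where the redox call held in all 9. In the fits on 12 animals the oxidative phosphorylation and immediate early calls held in all 12, the redox call in 11 and the adipocyte call in 4. The subsets with and without liver transcripts each compare drip in 3 males with 1 animal on one side. There oxidative phosphorylation was called upward (9.13e-05 and 0.00531), the adipocyte (0.0710 and 0.180) and redox lists (0.0902 and 0.225) kept their direction uncalled, and the immediate early list pointed upward (0.282 and 0.00419). The estimated correlation was at least 0.232 in the adipocyte, oxidative phosphorylation and immediate early lists, so those calls may arise from members that move together. It was -0.0069 in the redox list, below the preset 0.01, which argues against it there, though an estimate from 9 animals is imprecise. The redox call was still lost in camera with the estimated correlation (adjusted p = 0.121), so a raised correlation is not the reason for that loss. Splits of the same 9 animals called 4 or more lists 73 times in 100, with 13 the highest other count, so chance is not excluded for any of them. For sex the real count was 3 lists, 78 of 100 splits called as many, the highest other count was 12, and chance is not excluded.

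The interaction of PRKAG3 in the region tables fell from 1.04 ± 0.31 to 0.091 ± 0.26 with the liver split as a term, so the split may account for it. In females the split and the drip group coincide by the region labels, and the estimate of the split then rests on males. With the drip labels of the whole-genome records, which the match and the names of the tables go against, they do not coincide. The interaction then fell only from 0.82 ± 0.34 to 0.45 ± 0.21, so under those labels the split may account for only part of it. The tables do not show whether the lower level of PRKAG3 in libraries with liver transcripts has a technical or a biological source.

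For the counts of genes, 0 passed in the whole-genome drip fit, the region drip fit, the region interaction and the sex fit, so all 100 of 100 splits gave as many by construction, which tests nothing, and chance is not excluded. The highest other counts were 4, 0, 4 and 102. The sex split with 102 puts 3 females, 3 males, 3 high drip animals and 2 libraries with liver transcripts in one group of 6, which may reflect a structure of the samples that follows neither sex nor drip and was not tested.

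Low drip replicate 3, the only low drip female in the whole-genome drip fit, stood apart from the other low drip animals for ATP6V0D1 (92.6 CPM against 26.6 to 33.1), IRS1 (101 against 35.0 to 42.2), SLC25A25 (412 against 144 to 168), CHGA (8.48 against 0.0889 to 1.49) and PLIN4 (235 against 146 to 155). PLIN4 in this animal was 239 CPM against 82.8 to 127 in the other females. ATP6V0D1, IRS1, SLC25A25 and PLIN4 were named for a small p in the whole-genome interaction, where this animal is the only low drip female. CHGA was named for a small p in the drip fit, which also held this animal. The choice of these genes thus favoured values that stand apart here, and they give no separate evidence about the animal. Low drip replicate 5 had 27.8 CPM of FBLN2 against 34.3 to 35.0, and its region features took 0.848% of alignments against 0.940% to 0.982% in the other low drip animals. Among males, high drip replicate 5 had 1983 CPM of ANK1 against 2310.2 to 2503 and 44.8 CPM of TLN2 against 34.0 to 35.5. High drip replicate 6 had 90.5 CPM of FAM174A against 68.1 to 75.4 and 7.93 CPM of PLEKHB1 against 1.10 to 1.98. In the region tables SLC20A2 was 983 CPM in high drip replicate 4 against 345 to 455 and INPP5A 3138 CPM in low drip replicate 2 against 1929 to 2361.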

How the results depend on the processing

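Alternatives that use the liver transcript split, the region fits with other labels, and the region test on Ensembl genes alone, were chosen after seeing the data, and the cause of each change was not tested except where stated. The region drip count stayed at 0 in all alternatives, also with the drip labels of the whole-genome records, under which the region interaction stayed at 0 too, as it did in the 9 animals without a conflict. The whole-genome drip count of 0 became 5 with DESeq2, 2 in libraries with liver transcripts and 22 in the 4 libraries without, where 1 residual degree of freedom is left. Leaving out 1 animal gave 0 to 2 genes for drip (2 without low drip replicate 4), 0 to 1 for the whole-genome interaction (1 without high drip replicate 5) and 0 to 4 for the region interaction (4 without high drip replicate 4 and 3 without low drip replicate 4). The whole-genome interaction could not be fitted without low drip replicate 3, the only low drip female. The sex count of 0 became 13 with DESeq2, 1 with no filter, 2 in libraries with liver transcripts and 1 in those without, and stayed at 0 without any 1 animal.

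The 4 drip lists became 0 with an estimated correlation, 0 with fry, 2 with the tables as recorded, both of the 4, and 2 in libraries with liver transcripts, where 1 of the 4, oxidative phosphorylation, and the extracellular matrix were called. They became 5 in libraries without liver transcripts (2 of the 4, 1 of these reversed, with slow fibre up and macrophage and satellite cell markers down). They also became 5 in all 12 animals by best match (the 4, and glycogen and glycolysis up), 5 with age added (the 4, and fibroblast markers down) and 5 by best match with the liver split added (3 of the 4, with extracellular matrix and costamere genes down). Leaving out 1 animal gave 3 to 8 lists, with 8 without high drip replicate 4, where 5 lists outside the 4 were called. The adipocyte and redox lists stayed called in all 9 of these fits, the oxidative phosphorylation list in 5 and the immediate early list in 3. The immediate early list turned upward in libraries without liver transcripts (adjusted p = 0.00419) and pointed upward, uncalled, in those with them (0.282). By construction both subsets hold females of 1 drip level only, so drip is compared there in males alone, with low drip replicate 4 as the only low drip male without liver transcripts and high drip replicate 4 as the only high drip male with them. Over its alternatives the adjusted p of this list ranged up to 0.951. The 3 sex lists became 0 with an estimated correlation and 0 with fry, and leaving out 1 animal gave 0 to 4 lists (0 without high drip replicate 3 or 4, and 1 without high drip replicate 1, low drip replicate 3 or low drip replicate 4). The region share of 2.19% became 0% on Ensembl genes alone (permutation p = 0.0214) and passed no threshold in the other 4 alternatives. Among 28 genes named for drip, 33 of 639 values changed sign, all of them short of the threshold. RLE in place of TMM moved the median of all genes by under 0.01. In the region tables a count of 3 is up to 19.9 CPM in low drip females.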

Other observations

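The region share of alignments had a mean of 0.958% over the 12 animals, from 0.848% to 1.07%. Reads outside features made up 24.2% to 29.3% of alignments and reads that align to several places 12.8% to 15.5%. The 10 most abundant genes took 26.6% to 31.2% of gene counts.

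In the fit on all 12 animals with tables taken by match, the genes with the smallest p for drip after SLC30A2, FKBP5 and AGT were GSTA4, a glutathione transferase (3.98 ± 0.606 CPM in 6 high against 6.45 ± 1.57 CPM in 6 low drip animals), SYNPO2L, a sarcomere protein (339 ± 67.8 against 441 ± 46.5 CPM), and ACTB, cytoplasmic actin (281 ± 55.0 against 211 ± 29.8 CPM). NAMPT, which makes a precursor of NAD, was at 233 ± 22.8 against 340 ± 83.2 CPM. None passed, and the edgeR adjusted p was 0.999 for each.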
